A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

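Messenger RNA levels were compared among 5 lines of budding yeast, MA-A0, MA-A1, MA-A3, MA-A4 and MA-A8, on 10 dual-colour spotted arrays. MA stands for mutation accumulation, the propagation of a strain through repeated bottlenecks so that mutations are kept with little selection. Per the labels, total RNA of one line was labelled with Cy5 and that of another with Cy3 through a dendrimer kit, and each of the 10 pairs of lines was hybridised once. Every line therefore lay on 4 arrays, 2 with each dye. The labels do not say whether the 4 hybridisations of a line came from separate cultures, so the errors and p-values given here measure the spread between hybridisations. The number of arrays limits the precision.

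The deposited table holds 1 value per probe row and array, with positive and negative values from -5.54 to 4.17, and it was read as the log2 ratio of channel 1 (Cy5) to channel 2 (Cy3). Neither the base of the logarithm nor the direction is stated by the authors. Base 10 was set aside, because a ratio of 2 scanner values of 16 bits cannot exceed 4.82 on that scale. This assumes such a scanner and values of at least 1, which subtraction of background could undercut. Natural logarithms were not excluded. The direction follows the order in which each array names its lines. The arrays can be checked against one another, since any pair of lines is linked through the other 3. Among 512 choices of the arrays' signs the labelled choice left the 2nd smallest residual sum of squares, 1565, against a median of 3160 and a lowest of 1439 with the MA-A0 against MA-A8 array turned. This shows that the other 9 arrays run the same way, but not which way, and with the opposite reading every sign given here would turn. The scanner, background subtraction, spot filtering and any normalization are not given in the sources used here.

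The table has 7744 probe rows, of which 872 were empty on every array and 5961 had values on all 10. Values were present for 6282 to 6824 rows per array (81.1% to 88.1%). The annotation names a gene for 6116 rows, and 6111 of these were matched by gene ID to the R64 annotation of the S288C genome, which was used for symbols and gene order only. Rows of the same gene were averaged (33 genes, 12 of them controls with 33 rows each). The 1628 rows without a name were left out of the comparisons. Genes with values on at least 8 arrays were tested, which gave 5415 genes, 5131 of them with values on all 10 arrays.

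The medians of the arrays ran from -0.84 to 0.41, so the values had not been centred by the authors, and each array was centred on its median before the fit. This rule had been set for a table found not to be centred. The alternative planned as centring therefore became the values as deposited, without centring.

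For each gene a linear model was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). Its terms were the Cy5 line minus the Cy3 line and a dye effect, which left 5 residual degrees of freedom, and variances were moderated towards a common prior worth 9.19 degrees of freedom. Differences among the 5 lines were tested with limma's moderated F test, and limma's moderated test was used for the 10 pairs and for each line against the mean of the other 4 lines. A shift in a single line enters the values of each other line in diluted form and with the opposite sign, by construction. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, and genes passed at 0.05. The median residual standard deviation of a gene was 0.21 on the log2 scale, and 275 genes had a dye effect. Each value compares 2 lines on the same array, so the fit uses this pairing, and no pair of lines was hybridised on more than a single array.

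For groups of genes, 31 lists of pathways, complexes and regulons were fixed before the data were examined. Each list with at least 3 members on all arrays was tested in each line against all other genes with limma's camera, with an inter-gene correlation preset to 0.01, and again with a correlation estimated from the residuals. The same was done for the genes of each of the 16 nuclear chromosomes. The share of members differing among the lines was compared with that of all other genes tested by Fisher's exact test, 2-sided. That test takes genes as independent, which they are not, so its p-values may be too small. Genes along a chromosome were also summarised as medians of bins of 15 neighbouring genes.

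Genes are named by a rule set before the data were examined. It takes the 25 genes with the largest range among the lines that passed the F test with values on all arrays, the 3 highest and 3 lowest passing genes of each line, the largest passing difference in each direction of each pair, and up to 4 members of each list with the smallest p-value of the F test. Genes named outside the rule are said to be so.

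The model was tested on simulated data with 200 changed genes and noise drawn independently for each gene and array. Changes of 0.5 on the log2 scale were found for 40 of 67 genes, changes of 1 for 67 of 67 and changes of 2 for 66 of 66. Of 5215 unchanged genes 15 were called (0.288%). These 15 made up 7.98% of the calls, a larger share than the threshold for adjusted p-values aims at. A chromosome shifted by 0.25 in the simulation was estimated at 0.26. The simulation held no trend along the probe order and no correlation between genes, so its rates need not hold for the real arrays.

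The alternatives tried were the model without the dye term, values as deposited, values scaled to a common spread, genes with values on all arrays, every gene that could be fitted, array weights, a robust prior, the unmoderated test, each array left out in turn, the estimated correlation, camera on the ranked statistics of all genes tested, members taken at an unadjusted p, and chromosome medians without the listed genes. After the data had been examined, 3 kinds were added: centring within 16 blocks of 484 consecutive probe rows, the sign of the MA-A0 against MA-A8 array turned, and tests without genes on shifted chromosomes.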

Results

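Transcript levels were compared among 5 mutation-accumulation lines of budding yeast, MA-A0, MA-A1, MA-A3, MA-A4 and MA-A8, to see how far the transcriptomes of such lines had diverged from one another. Each of the 10 pairs of lines shared 1 array, so each line was measured on 4 arrays, 2 with each dye. The labels name no ancestor of the lines, so a difference between lines does not show which of them had changed. Between 6282 and 6824 probe rows had a value per array, and 5415 genes were tested. The values were read as log2 ratios of the Cy5 line to the Cy3 line, a base and a direction that the deposited table does not state. With the opposite direction every higher would read lower. Signed values of a line are its difference from the mean of the other 4 lines, with the standard error of the fit, resting on 10 arrays where no value was missing, 4 of them with that line. AGA1, AAD15 and COS12 had no value on MA-A0 against MA-A4 and rest on 9 arrays, 3 with MA-A0 and 3 with MA-A4. Unless another test is named, p-values are from limma's moderated tests, adjusted over all genes tested.

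The general stress gene HSP12, which encodes a small membrane-binding protein of stressed cells, had the widest range of the genes named by range: it was 3.88 ± 0.22 higher in MA-A3 than in MA-A8, a 14.7-fold difference if the base is 2. DDR2, another stress-induced gene, spanned 3.25 ± 0.22, and YGP1, which encodes a secreted glycoprotein made on nutrient limitation, spanned 2.67 ± 0.17. FIT2 and FIT3, which encode cell wall mannoproteins that help retain siderophore iron, went the other way and were lowest in MA-A3, with ranges of 2.43 ± 0.32 and 2.37 ± 0.27. Of the 25 genes with the widest range, 22 deviated most in MA-A3, 20 were highest there and 17 were lowest in MA-A8. In all, 1014 of 5415 genes (18.7%) differed among the lines by the F test, with a median range of 0.71, and 1893 did at an unadjusted p under 0.05. MA-A3 was the highest line for 486 of them and the lowest for 262. The count depended on single arrays: it was 1906 without MA-A0 against MA-A8, 641 without MA-A3 against MA-A0 and 591 without MA-A3 against MA-A1. The 174 results for named genes include members of lists that did not pass in the fit used here. Of those that passed, 137 no longer did with the unmoderated test, 84 with values as deposited, 34 with the sign of the MA-A0 against MA-A8 array turned and 31 without the dye term. Leaving out 1 array ended up to 35 of them, the most without MA-A3 against MA-A1. No named gene that passed changed sign under any alternative, but these genes were chosen from the same data for large differences or small p-values.

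**Figure D1:**
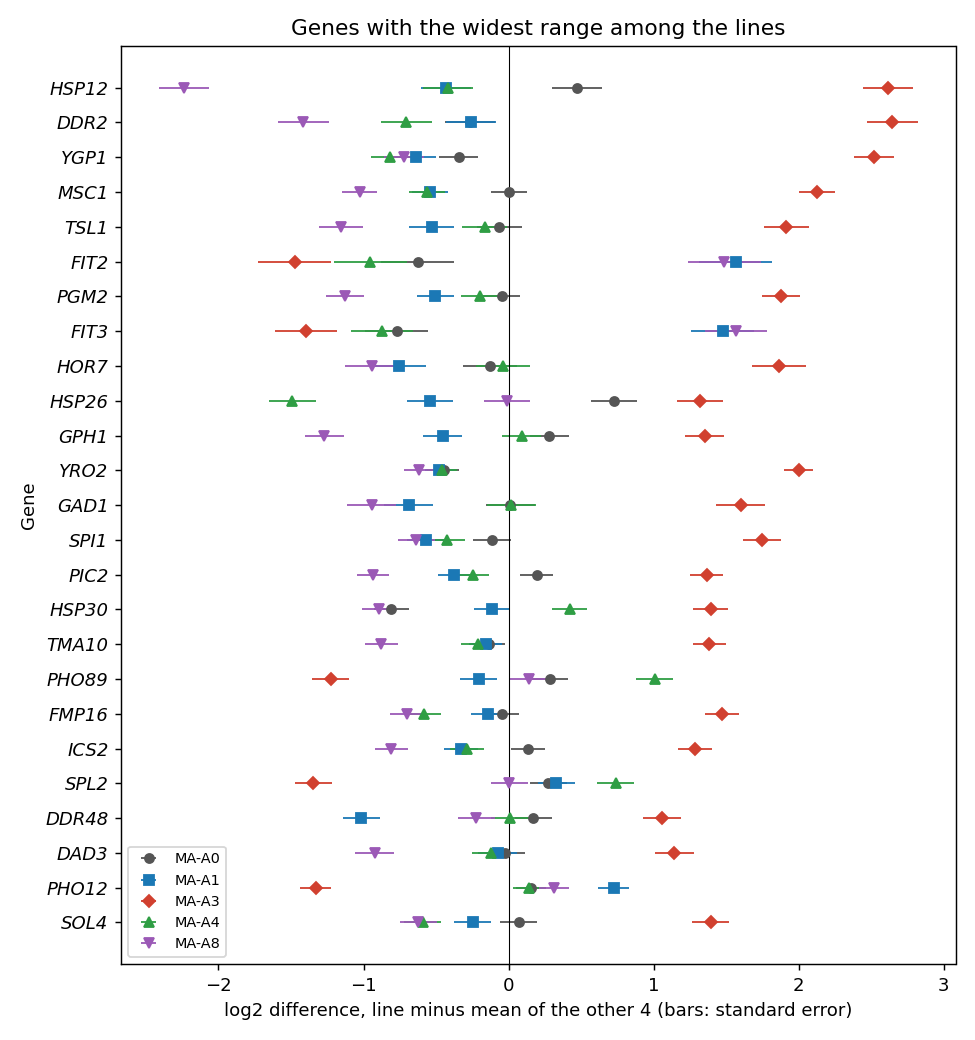
Difference of each line from the mean of the other 4 lines (horizontal axis, log2, direction read as Cy5 over Cy3) for the 25 genes with the widest range among the lines, with bars for the standard error. MA-A3 lies to the right for most genes, up to 2.65 for DDR2, and to the left for FIT2, FIT3, PHO89, SPL2 and PHO12.

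Groups of genes differed in how many members varied among the lines. The p-values of Fisher's exact test given here take genes as independent, which they are not, and may be too small. In the list of general stress and storage carbohydrate genes 25 of 40 measured members passed the F test (29 adjusted over the list alone), against 18.4% of all other genes (Fisher's exact test over 31 lists, adjusted p = 3.5e-08). Among the Gcn4 targets of amino acid biosynthesis 28 of 54 passed (36 adjusted over the list alone, adjusted p = 5.8e-07), and in the phosphate regulon, the Pho4-controlled genes of phosphate uptake, 12 of 19 did (15 adjusted over the list alone, adjusted p = 0.000186). Oxidative phosphorylation had 18 of 36 passing (23 adjusted over the list alone, adjusted p = 0.000186), and the iron regulon, driven by Aft1 when iron is scarce, had 12 of 26 (15 adjusted over the list alone, adjusted p = 0.00649). Histones had 6 of 10 (7 adjusted over the list alone, adjusted p = 0.0198), genes specific to mating type a had 5 of 8 (5 adjusted over the list alone, adjusted p = 0.0299) and ergosterol synthesis had 11 of 27 (13 adjusted over the list alone, adjusted p = 0.0349). Cytosolic ribosomal proteins varied less often than other genes, with 8 of 127 members passing, fewer than for the remaining genes (adjusted p = 0.00047), and with limma's F test adjusted over the list alone 0 passed. The call for oxidative phosphorylation ended without MA-A1 against MA-A0 (adjusted p = 0.0754), and turning the sign of the MA-A0 against MA-A8 array also ended it (adjusted p = 0.125). The calls for histones, a-specific genes and ergosterol synthesis each ended in several fits. Turning the sign of the MA-A0 against MA-A8 array ended the call for histones (adjusted p = 0.750) and turned the excess of a-specific genes to -3.39 percentage points. Calls for a-specific genes and ergosterol synthesis ended with centring within blocks of probe rows (0.081 each) and with members taken at an unadjusted p (0.251 and 0.0968). Without MA-A8 against MA-A3 their adjusted p-values were 0.333, 0.0553 and 0.655, without MA-A1 against MA-A0 they were 0.379, 0.0851 and 0.15. Without MA-A8 against MA-A1 they were 0.0862, 0.0546 and 0.192. Without MA-A1 against MA-A4 histones and a-specific genes were lost (0.888 and 0.0679), without MA-A3 against MA-A1 histones and ergosterol synthesis (0.244 and 0.285), and without MA-A0 against MA-A8 a-specific genes and ergosterol synthesis (0.288 and 0.230). Ergosterol synthesis was also lost without MA-A0 against MA-A4 (0.0928), MA-A4 against MA-A3 (0.112) or MA-A3 against MA-A0 (0.456). The difference in percent passing moved over 1.5 times while the call held for oxidative phosphorylation (from 31.5 points to 54.1 without MA-A0 against MA-A8, 20.1 without MA-A8 against MA-A3, 20.5 without MA-A8 against MA-A1 and 17.0 without MA-A3 against MA-A1), for Gcn4 targets (from 33.5 to 21.2 without MA-A1 against MA-A4, 20.6 without MA-A8 against MA-A1 and 20.8 without MA-A3 against MA-A1), for histones (62.3 without MA-A4 against MA-A8) and for ribosomal proteins (-19.1 without MA-A0 against MA-A8). With genes on the chromosomes described further on left out, ergosterol synthesis kept 3 of 16 passing (adjusted p = 0.393).

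MA-A3 was the most divergent line by the number of genes that differed. The stress genes DDR2, HSP12 and YGP1 were higher there by 2.65 ± 0.17, 2.62 ± 0.17 and 2.52 ± 0.14 (adjusted p = 4.1e-07, 4.1e-07 and 7.2e-08). They were joined by MSC1 (2.13 ± 0.12), TSL1, a subunit of trehalose synthase (1.92 ± 0.15), and PGM2, phosphoglucomutase (1.88 ± 0.13). Lower in MA-A3 were FIT2 by -1.48 ± 0.25, FIT3 by -1.40 ± 0.21 and the secreted acid phosphatase gene PHO11 by -1.37 ± 0.13, whose probe may also read the near-identical PHO12 (-1.33 ± 0.11). The largest adjusted p of these 3 was 0.000761, for FIT2, and with a robust prior it was 0.0554. In total 584 genes were higher and 335 lower in MA-A3 than in the mean of the other lines, and 1548 of 5415 had an unadjusted p under 0.05. Of the higher genes 351 lie on chromosome XIII, described further on, and outside it 233 genes were higher and 326 lower. Without genes on the shifted chromosomes the total was 361 of 4120 (159 higher and 202 lower), still the most of any line. The total of 919 was 565 without MA-A3 against MA-A0 and 568 without MA-A3 against MA-A1.

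Of the 40 general stress and storage carbohydrate genes 27 were higher in MA-A3 and 13 did not pass (29 higher and 1 lower adjusted over the list alone). Their median was 0.58 (camera, adjusted p = 6.1e-20, adjusted p = 0.262 with an estimated correlation). Of the 27 genes 8 lie on chromosome XIII. Among the Gcn4 targets of amino acid biosynthesis 27 of 54 were lower and 1 higher (29 and 1 adjusted over the list alone), with a median of -0.31 (adjusted p = 4.8e-11, adjusted p = 0.140 with an estimated correlation). GDH1, the glutamate dehydrogenase that assimilates ammonium, was at -0.70 ± 0.09, and the lysine genes LYS1 and LYS9 were at -0.59 ± 0.11 and -0.48 ± 0.10. The phosphate regulon had 11 of 19 members lower and 2 higher (12 and 2 adjusted over the list alone), with a median of -0.63 (adjusted p = 6.4e-07, adjusted p = 0.157 with an estimated correlation). SPL2, which restrains low-affinity phosphate uptake, was at -1.35 ± 0.13 and the phosphate transporter gene PHO89 at -1.23 ± 0.13, whereas PHM8 was higher by 0.93 ± 0.11. In the iron regulon 8 of 26 were lower and 2 higher (10 and 2 adjusted over the list alone, median -0.19, adjusted p = 0.00262, adjusted p = 0.47 with an estimated correlation), among them the siderophore transporter gene SIT1 at -0.95 ± 0.15.

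Of 36 oxidative phosphorylation genes 10 passed in MA-A3, each of them higher and 5 of them on chromosome XIII (14 adjusted over the list alone, median 0.20, adjusted p = 1.1e-06, adjusted p = 0.649 with an estimated correlation). The NADH dehydrogenases NDE1 and NDI1 were at 1.17 ± 0.12 and 1.03 ± 0.11 and the lactate dehydrogenase CYB2 at 1.23 ± 0.13, all 3 encoded on chromosome XIII. Without MA-A4 against MA-A3 the median of this list was 0.33. Mitochondrial ribosomal proteins had 8 of 63 members higher (8 adjusted over the list alone, median 0.16, adjusted p = 9.9e-06, adjusted p = 0.605 with an estimated correlation). Of the 8 members 7 lie on chromosome XIII, whereas the median without genes on the shifted chromosomes was still 0.16 (adjusted p = 9.0e-06). The histones had 7 of 10 higher (8 adjusted over the list alone, median 0.37, adjusted p = 0.00262, adjusted p = 0.566 with an estimated correlation), a call that ended without the dye term (adjusted p = 0.0736). Glycolysis and fermentation had 8 of 25 lower and 3 higher (16 and 3 adjusted over the list alone, median -0.48, adjusted p = 0.0036, adjusted p = 0.71 with an estimated correlation). The 3 included the hexokinase gene HXK1 (0.64 ± 0.16) and the glucokinase gene GLK1 (0.41 ± 0.13, lost from the F test without MA-A1 against MA-A4 at an adjusted p of 0.0759), which are induced when glucose runs low. The median was -0.32 without MA-A4 against MA-A3, and without MA-A3 against MA-A1 it was -0.31 and the call ended (adjusted p = 0.0908). Cytosolic ribosomal proteins had a median of -0.14 with 5 of 127 lower and 1 higher (1 and 1 adjusted over the list alone, adjusted p = 0.00348, adjusted p = 0.803 with an estimated correlation). This rested on single arrays, as it was -0.03 without MA-A4 against MA-A3 (adjusted p = 0.40), -0.07 without MA-A3 against MA-A1 (0.206) and -0.25 without MA-A3 against MA-A0.

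MA-A8 lay at the other end for the stress genes. HSP12, DDR2 and the glycogen phosphorylase gene GPH1 were lower there by -2.24 ± 0.17, -1.42 ± 0.17 and -1.27 ± 0.13 (adjusted p = 1.6e-05, 0.00084 and 0.000465). FIT3 and FIT2 were higher by 1.57 ± 0.21 and 1.49 ± 0.25, together with YDL241W, a gene of unknown function, by 0.94 ± 0.11. FIT2 no longer passed without MA-A8 against MA-A1 (1.16, adjusted p = 0.134) or with a robust prior (0.117), and YDL241W no longer passed with values as deposited (0.0901). Turning the sign of the MA-A0 against MA-A8 array ended all 6 of these calls, with adjusted p-values from 0.0549 for DDR2 to 0.365 for FIT3. Among the other genes named by list, the drug efflux pump gene PDR5 was at 0.82 ± 0.13 and HUG1, which is induced by DNA damage, at 0.89 ± 0.14. In MA-A8 71 genes were higher and 109 lower, 180 in total, and 1066 had an unadjusted p under 0.05. That total was 81 without MA-A4 against MA-A8, 90 without MA-A8 against MA-A3, 33 without MA-A8 against MA-A1 and 111 without MA-A3 against MA-A1. Outside the shifted chromosomes 52 genes were higher and 58 lower in MA-A8.

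General stress and storage carbohydrate genes had 19 of 40 members passing in MA-A8, each of them lower (26 lower and 1 higher adjusted over the list alone), and a median of -0.42 (adjusted p = 4.5e-17, adjusted p = 0.262 with an estimated correlation). Oxidative phosphorylation had 5 of 36 passing, each lower (11 adjusted over the list alone, median -0.17, adjusted p = 1.2e-06, adjusted p = 0.649 with an estimated correlation), with medians of -0.09 without MA-A8 against MA-A3 and -0.29 without MA-A0 against MA-A8. Gcn4 targets were higher, with 6 of 54 passing, each higher (12 adjusted over the list alone, median 0.17, adjusted p = 9.5e-08, adjusted p = 0.157 with an estimated correlation), among them GDH1 at 0.58 ± 0.09 and LYS1 at 0.55 ± 0.11. Heat shock chaperones had 3 of 29 passing, each higher (7 adjusted over the list alone, median 0.23, adjusted p = 1.5e-06, adjusted p = 0.592 with an estimated correlation), among them the Hsp110 gene SSE1 (0.58 ± 0.12) and the mitochondrial Hsp70 gene SSC1 (0.45 ± 0.11). Their median was 0.14 without MA-A0 against MA-A8 and 0.13 without MA-A8 against MA-A1. SSE1 and SSC1 no longer passed the F test without MA-A8 against MA-A1 (adjusted p = 0.0764 and 0.0792), and SSE1 was at 0.38 without MA-A0 against MA-A8. With the sign of that array turned the list was at 0.10 and did not pass (adjusted p = 0.154). Drug resistance genes had 2 of 16 passing, each higher (7 adjusted over the list alone, median 0.17, adjusted p = 0.000134, adjusted p = 0.262 with an estimated correlation), with a median of 0.11 without MA-A4 against MA-A8. Subtelomeric families had 1 of 42 higher (7 adjusted over the list alone, median 0.16, adjusted p = 7.3e-07, adjusted p = 0.262 with an estimated correlation). Histones were lower at a median of -0.29 with 1 of 10 passing (7 adjusted over the list alone, adjusted p = 0.000426, adjusted p = 0.47 with an estimated correlation). Their median was -0.47 without MA-A4 against MA-A8 and -0.18 without MA-A0 against MA-A8. Cytosolic ribosomal proteins had a median of -0.16 (adjusted p = 2.3e-06, adjusted p = 0.717 with an estimated correlation), with no single member passing limma's test. The call ended without MA-A0 against MA-A8 (-0.02, adjusted p = 0.849). It was -0.31 without MA-A4 against MA-A8 and -0.10 without MA-A8 against MA-A3. With the sign of the MA-A0 against MA-A8 array turned ribosomal proteins were at 0.07 and histones at 0.01, and Gcn4 targets and subtelomeric families were reduced to 0.06 and 0.10.

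In MA-A1 the iron genes FIT2, FIT3 and FIT1 were higher by 1.57 ± 0.25, 1.48 ± 0.21 and 0.92 ± 0.18 (adjusted p = 0.0103, 0.00658 and 0.0183). The copper metallothionein genes CUP1-1 and CUP1-2, near-identical copies that one probe may not tell apart, were lower by -1.10 ± 0.13 and -1.08 ± 0.14, and the stress gene DDR48 by -1.02 ± 0.13 (adjusted p = 0.0039, 0.00418 and 0.0039). None of the 6 held in every fit. Without MA-A3 against MA-A1 their adjusted p-values ran from 0.0565 for DDR48 to 0.155 for FIT1. Without MA-A1 against MA-A4 all but FIT3 were lost (DDR48 at 0.0655). Leaving out MA-A1 against MA-A0 ended the calls of the 3 FIT genes, with FIT3 at 0.0706, and leaving out MA-A8 against MA-A1 ended those of FIT3 and DDR48 (0.0508 each). Without the dye term FIT1 and both CUP1 copies missed the threshold (0.051 and 0.0556). FIT2 did so with a robust prior (0.0845), FIT3 with the sign of the MA-A0 against MA-A8 array turned (0.0674) and FIT1 with values as deposited (0.503). In MA-A1 100 genes were higher and 106 lower, 206 in total, with 1156 at an unadjusted p under 0.05. That total was 380 without MA-A0 against MA-A4, 576 without MA-A0 against MA-A8, 71 without MA-A3 against MA-A0, 4 without MA-A1 against MA-A0, 2 without MA-A1 against MA-A4 and 7 without MA-A8 against MA-A1. Without MA-A3 against MA-A1 limma's test called 0 genes, with 822 at an unadjusted p under 0.05. Much of the total lay on the shifted chromosomes, with 69 of the higher genes on XII and 34 of the lower on XIII. Outside the shifted chromosomes 23 genes were higher and 67 lower in MA-A1, and 15 and 27 when only those genes were tested.

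Several lists of respiration, protein turnover and stress had lower medians in MA-A1. Oxidative phosphorylation had 7 of 36 passing, each lower (24 adjusted over the list alone, median -0.33, adjusted p = 2.6e-10, adjusted p = 0.592 with an estimated correlation). Proteasome subunits had 5 of 34 passing, each lower (14 lower and 1 higher adjusted over the list alone, median -0.24, adjusted p = 5.4e-07, adjusted p = 0.605 with an estimated correlation), among them PRE5 at -0.58 ± 0.11, which no longer passed the F test without MA-A8 against MA-A1 (adjusted p = 0.0566) or MA-A3 against MA-A1 (0.0922). General stress and storage carbohydrate genes had 6 of 40 passing, each lower and 4 of them on chromosome XIII (11 adjusted over the list alone, median -0.24, adjusted p = 1.6e-06, adjusted p = 0.573 with an estimated correlation). The excess of this list in MA-A3 enters its value in MA-A1 with the opposite sign. Its means were 0.90 in MA-A3, -0.27 in MA-A1 and -0.008 in MA-A0. How much of the call is particular to MA-A1 was not tested. Mitochondrial ribosomal proteins had 4 of 63 passing, each lower and 3 of them on chromosome XIII (10 adjusted over the list alone, median -0.18, adjusted p = 1.5e-06, adjusted p = 0.592 with an estimated correlation), and histones had 1 of 10 (2 adjusted over the list alone, median -0.28, adjusted p = 0.00055, adjusted p = 0.47 with an estimated correlation). Heat shock chaperones had 1 of 29 lower (8 adjusted over the list alone, median -0.23, adjusted p = 0.00389, adjusted p = 0.71 with an estimated correlation). The call was lost without MA-A1 against MA-A4 (adjusted p = 0.0587) or without MA-A8 against MA-A1 (median -0.12, adjusted p = 0.156), with a median of -0.35 without MA-A1 against MA-A0. The iron regulon was higher, with 7 of 26 passing, each higher (13 adjusted over the list alone, median 0.33, adjusted p = 6.4e-07, adjusted p = 0.262 with an estimated correlation). With genes on the shifted chromosomes left out its median was 0.18. Cytosolic ribosomal proteins were higher at a median of 0.14 with 1 of 127 passing (adjusted p = 4.5e-10, adjusted p = 0.71 with an estimated correlation; 0 with limma adjusted over the list alone), and the median was 0.07 without MA-A3 against MA-A1.

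In MA-A4 the gene with the highest value among those that passed was MET17, the enzyme that fixes sulphide into homocysteine, at 1.37 ± 0.13 (adjusted p = 0.000217). PHO89 and the amino acid permease gene DIP5 were also higher, by 1.01 ± 0.13 and 0.89 ± 0.11, calls that ended with values as deposited (adjusted p = 0.115 and 0.508). The small heat shock protein gene HSP26 was lower by -1.49 ± 0.16 (adjusted p = 0.000512), and the aryl alcohol dehydrogenase genes AAD3 and AAD15, members of a family of similar sequence, by -1.0 ± 0.12 and -0.91 ± 0.15. AAD15 missed the threshold without MA-A4 against MA-A3 (-0.69, adjusted p = 0.0573) and without MA-A1 against MA-A4 (-1.06, adjusted p = 0.086), and with values as deposited (0.998). In MA-A4 93 genes were higher and 101 lower, 194 in total, with 790 at an unadjusted p under 0.05. The total was 96 without MA-A0 against MA-A4, 42 without MA-A4 against MA-A3, 16 without MA-A1 against MA-A4, 101 without MA-A4 against MA-A8, 310 without MA-A0 against MA-A8, 125 without MA-A8 against MA-A1 and 129 without MA-A3 against MA-A1. Outside the shifted chromosomes 77 genes were higher and 53 lower in MA-A4. Genes of sulphur amino acid synthesis had 5 of 28 passing, each higher (10 higher and 1 lower adjusted over the list alone, median 0.17, adjusted p = 2.9e-06, adjusted p = 0.394 with an estimated correlation), among them the S-adenosylmethionine permease gene SAM3 (0.85 ± 0.11) and the methionine permease gene MUP1 (0.66 ± 0.11). The phosphate regulon had 7 of 19 passing, each higher (9 adjusted over the list alone, median 0.22, adjusted p = 9.8e-06, adjusted p = 0.20 with an estimated correlation). Their medians with values as deposited were 0.07 for sulphur genes and 0.12 for the phosphate regulon, where that of all genes was -0.08. Subtelomeric families had 6 of 42 passing, each lower (11 adjusted over the list alone, median -0.16, adjusted p = 1.6e-07, adjusted p = 0.262 with an estimated correlation), among them COS12 at -0.77 ± 0.17. Gcn4 targets had 4 of 54 passing, each higher (11 higher and 3 lower adjusted over the list alone, median 0.13, adjusted p = 0.00416, adjusted p = 0.287 with an estimated correlation), with a median of 0.08 without MA-A4 against MA-A3 and no call without MA-A4 against MA-A8 (adjusted p = 0.0710).

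The 3 highest of the genes that passed in MA-A0 act in mating. AGA1, the anchor of the a-agglutinin, was higher by 0.85 ± 0.11, ASG7 by 0.77 ± 0.10 and MFA1, which encodes the a-factor pheromone, by 0.76 ± 0.13 (adjusted p = 0.0104, 0.0104 and 0.0218). The list of a-specific genes had 3 of 8 passing, each higher (5 adjusted over the list alone, median 0.33, adjusted p = 7.9e-06, adjusted p = 0.418 with an estimated correlation), among them the agglutinin subunit gene AGA2 at 0.72 ± 0.10. The median of the list was 0.53 without genes on the shifted chromosomes. Lower in MA-A0 were the plasma membrane stress gene HSP30 (-0.81 ± 0.12), DIA1 (-0.68 ± 0.11) and ATG41 (-0.65 ± 0.09), with a largest adjusted p of 0.0184 for DIA1. DIA1 lies on chromosome XIII and was highest in MA-A3, whose shift of that chromosome enters MA-A0 with the opposite sign. In total 12 genes were higher and 6 lower, with 832 at an unadjusted p under 0.05. Outside chromosome XIII 12 were higher and 3 lower. The total of 18 rested on single arrays: it was 8 without MA-A0 against MA-A4, 6 without MA-A1 against MA-A4, 448 without MA-A0 against MA-A8, 11 without MA-A8 against MA-A1, 2 without MA-A3 against MA-A0 and 7 without MA-A3 against MA-A1. Without MA-A1 against MA-A0 limma's test called 0 genes, with 483 at an unadjusted p under 0.05. Of these 6 genes all but ASG7 were lost without MA-A3 against MA-A0 (AGA1 at 0.087), and MFA1 was lost in 3 further fits (0.0532 without MA-A3 against MA-A1, 0.0616 without MA-A0 against MA-A4 and 0.0734 without MA-A1 against MA-A4). HSP30 was lost without MA-A0 against MA-A4 (0.0683). The values as deposited ended the calls of AGA1, HSP30, DIA1 and ATG41 (adjusted p from 0.417 to 0.437). Without the dye term MFA1 did not pass (0.0577). With the sign of the MA-A0 against MA-A8 array turned, AGA1, ASG7 and MFA1 were at 0.30, 0.30 and 0.19 and did not pass, and neither did the list (median 0.16, adjusted p = 0.202). Oxidative phosphorylation was higher with 1 of 36 passing (5 adjusted over the list alone, median 0.20, adjusted p = 1.8e-07, adjusted p = 0.624 with an estimated correlation), at 0.13 without MA-A0 against MA-A4 and 0.34 without MA-A0 against MA-A8. The iron regulon had a median of -0.21 in MA-A0 (camera, adjusted p = 0.000178, adjusted p = 0.391 with an estimated correlation), with no member passing limma's test over all genes and 5 lower adjusted over the list alone. Without genes on the shifted chromosomes its median was -0.10 (camera, adjusted p = 0.0108). With values as deposited it turned to 0.07. There the median of all genes was itself displaced by 0.28 in MA-A0, -0.14 in MA-A1, -0.08 in MA-A4 and -0.07 in MA-A8. The 4 genes specific to mating type alpha, STE3, MF(ALPHA)2, SAG1 and MF(ALPHA)1, did not pass the F test, and the smallest adjusted p was 0.319 for STE3.

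Over the 150 combinations of list and line 56 passed with the preset correlation. With an estimated correlation 0 passed by camera, 17 had an unadjusted p under 0.05, and the adjusted p-values of the 56 lay between 0.140 and 0.803. In 17 combinations the median, mean and direction of the test did not share a sign, and 0 of these had passed camera with the preset correlation.

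**Figure D2:**
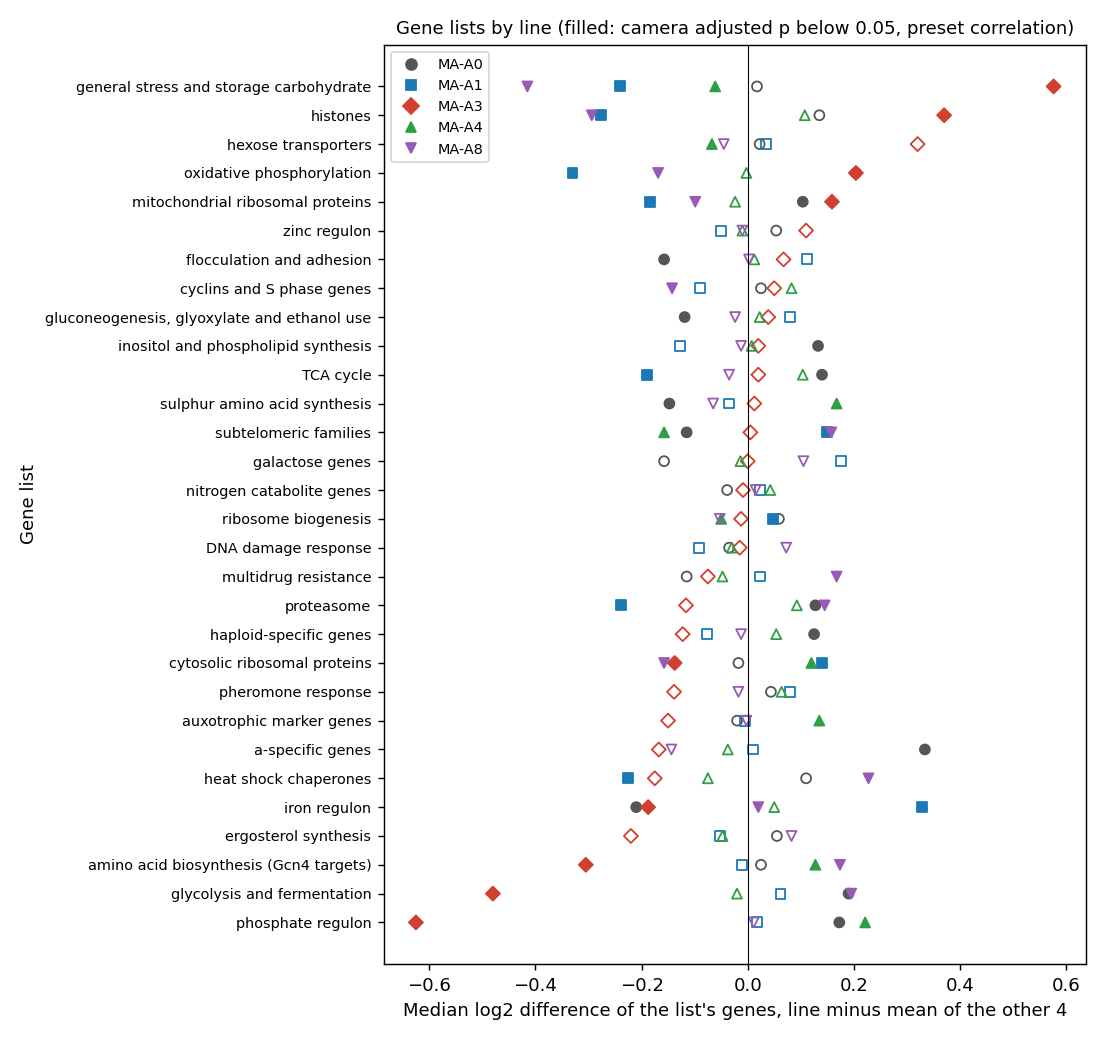
Median of the genes of each list in each line (horizontal axis, log2 difference from the mean of the other 4 lines, direction read as Cy5 over Cy3), filled where camera passed with the preset correlation. General stress genes run from -0.42 in MA-A8 to 0.58 in MA-A3, and the phosphate regulon is lowest in MA-A3 at -0.63. With values as deposited 5 lists of MA-A0, the ribosome biogenesis list of MA-A1 and the iron regulon of MA-A8 turn in sign. There the median of all genes is itself 0.28 in MA-A0, -0.14 in MA-A1 and -0.07 in MA-A8, and these lists stay on the same side of it.

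Genes of whole chromosomes were displaced together. In MA-A3 the genes of chromosome XIII had a median of 0.56, with 95.5% of 404 genes above 0 and 351 of 427 tested higher against 9 lower (camera, adjusted p = 1.9e-76, adjusted p = 0.0353 with an estimated correlation). Along this chromosome 27 of 27 bins of neighbouring genes lay above 0, from 0.36 to 0.73, and the stress genes MSC1, TSL1 and PGM2, the DNA repair genes RAD52 (0.81 ± 0.10) and OGG1 (0.65 ± 0.10) and the ergosterol gene ERG5 (0.75 ± 0.09) lie on it. In MA-A1 the genes of chromosome XII had a median of 0.25, with 89.4% of 414 genes above 0 and 69 of 445 higher against 2 lower (adjusted p = 1.1e-44, adjusted p = 0.0245 with an estimated correlation). Of its bins 27 of 28 lay above 0, up to 0.37. The median was 0.14 with values as deposited, where that of all genes was -0.14. ILV5 (0.67 ± 0.11) and TIS11 (0.77 ± 0.16) are among its genes. In MA-A4 the genes of chromosome IX had a median of -0.25 (8.76% of 137 genes above 0), with 25 of 149 tested passing, each lower (adjusted p = 2.1e-32, adjusted p = 0.0602 with an estimated correlation), and its 9 bins ranged from -0.29 to -0.22. Chromosome XI in MA-A1 had a smaller median of 0.11, with 77.3% of 264 genes above 0 and 5 of 274 passing, each higher (adjusted p = 2.1e-09, adjusted p = 0.244 with an estimated correlation). With values as deposited its median was -0.00125, still above the -0.14 of all genes. On each array that carried the line the chromosome was displaced from the other genes in the direction of that line, by a size of 0.50 to 0.71 for XIII, 0.25 to 0.40 for XII, 0.18 to 0.38 for IX and 0.08 to 0.24 for XI.

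In total 12 of 80 combinations of chromosome and line passed, and the other 8 were shifts of the same chromosomes in further lines. For XIII the medians were -0.19 in MA-A1, -0.17 in MA-A8, -0.10 in MA-A4 and -0.10 in MA-A0 (adjusted p = 0.244, 0.258, 0.299 and 0.299 with an estimated correlation), a direction that turned in MA-A0 with values as deposited (0.18). A shift of XIII in MA-A3 by itself enters the other lines with the opposite sign. XII had -0.09 in MA-A3 and -0.06 in MA-A0 (adjusted p = 0.258 each with an estimated correlation), a direction that turned in MA-A0 with values as deposited (0.22). The medians of XIII and XII in MA-A0 there stayed below that of all genes, which was 0.28. IX had 0.09 in MA-A0 and 0.09 in MA-A8 (adjusted p = 0.559 and 0.258 with an estimated correlation). The call for IX in MA-A0 ended without MA-A0 against MA-A8 (0.06, adjusted p = 0.433) and without MA-A3 against MA-A0 (0.08, adjusted p = 0.311), and the median was 0.06 without MA-A1 against MA-A0. It also ended with centring within blocks of probe rows (0.06, adjusted p = 0.0536), the sign of the MA-A0 against MA-A8 array turned (0.06, 0.169), camera on all genes tested (0.08, 0.0623) and values as deposited (0.37, 0.0664). With the estimated correlation 2 combinations passed and 14 had an unadjusted p under 0.05. Of the genes on IX, XI, XII and XIII 505 of 1295 (39.0%) differed among the lines by the F test, against 508 of 4104 (12.4%) on the other nuclear chromosomes. These chromosomes had been picked as displaced in the same data, and XIII alone held 326 of the 505 genes (76.3% of 427). The shares were 25.5% of 149 genes on IX and 25.6% of 445 on XII. Chromosome XI had 27 of 274 (9.85%), a smaller share than the other nuclear chromosomes. Tested without the genes of these 4 chromosomes, 428 of 4120 genes differed among the lines.

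**Figure D3:**
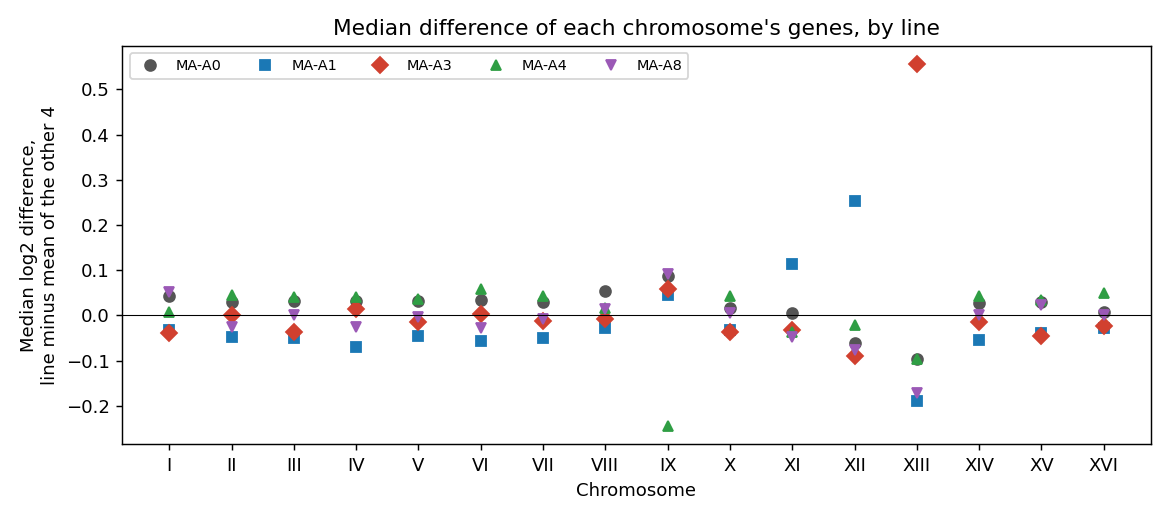
Median log2 difference from the mean of the other 4 lines (vertical axis, direction read as Cy5 over Cy3) of the genes of each nuclear chromosome (horizontal axis), by line. XIII in MA-A3 at 0.56, XII in MA-A1 at 0.25 and IX in MA-A4 at -0.25 lie apart from the rest. XI in MA-A1 is at 0.11. With values as deposited it is at -0.00125, where the median of all genes is itself -0.14.

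**Figure D4:**
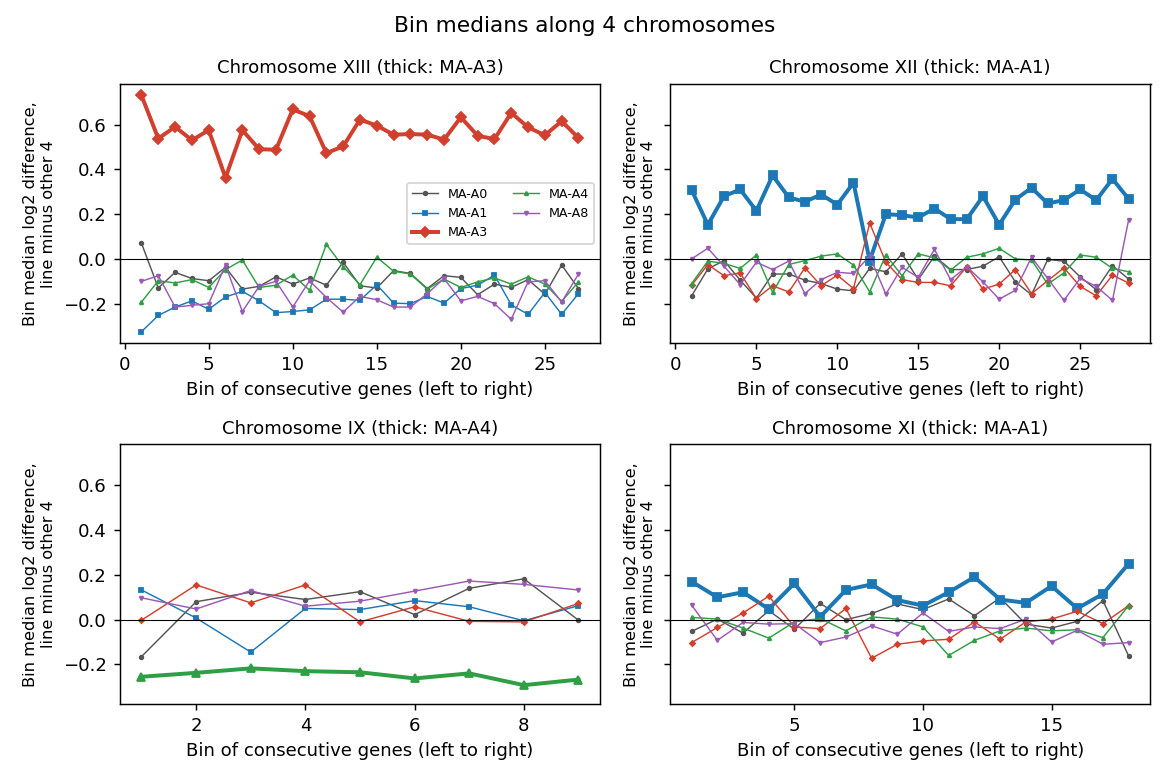
Medians of bins of 15 neighbouring genes (vertical axis, log2 difference from the mean of the other 4 lines) in order along chromosomes XIII, XII, IX and XI (horizontal axis), with the displaced line drawn thick. The displacement runs along each chromosome, with bins of XIII in MA-A3 from 0.36 to 0.73. With values as deposited the median of XI in MA-A1 turns in sign but stays above that of all genes, which is -0.14 there.

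Between pairs of lines, the genes with the largest differences recurred. HSP12 was the gene most in excess over MA-A8 in MA-A3 (3.88 ± 0.22, adjusted p = 2.3e-07), MA-A0 (2.17 ± 0.22, 0.00048), MA-A4 (1.45 ± 0.22, 0.00361) and MA-A1 (1.44 ± 0.22, 0.0146). FIT3 was the gene most in deficit against MA-A8 in MA-A3 (-2.37 ± 0.27), MA-A4 (-1.96 ± 0.27) and MA-A0 (-1.87 ± 0.27), and in MA-A1 it was CUP1-1 (-1.31 ± 0.17). Against MA-A3, MA-A1 had the largest excess in FIT2 (2.43 ± 0.32) and the largest deficit in YGP1 (-2.53 ± 0.17), and MA-A0 had them in PHO11 (1.42 ± 0.17) and DDR2 (-2.33 ± 0.22). Relative to MA-A4, MA-A3 was highest in DDR2 (2.68 ± 0.22) and lowest in PHO89 (-1.79 ± 0.16). MET17 was lowest relative to MA-A4 in MA-A0 (-1.57 ± 0.16) and MA-A1 (-1.45 ± 0.16), where HSP26 (1.77 ± 0.20) and FIT2 (2.01 ± 0.32) were highest. MA-A0 exceeded MA-A1 most in CUP1-1 (1.21 ± 0.17) and fell short most in FIT3 (-1.80 ± 0.27). The largest adjusted p of these 20 differences was 0.0146. They were chosen as the largest in these data, so their signs had little room to turn. None of them turned in any alternative, but only 6 passed in all: PHO11 and DDR2 between MA-A0 and MA-A3, YGP1 between MA-A1 and MA-A3, DDR2 and PHO89 between MA-A3 and MA-A4 and HSP12 between MA-A3 and MA-A8. The unmoderated test ended 13 of the 20 and the turned sign of the MA-A0 against MA-A8 array 8, among them both for MA-A0 and MA-A8 (HSP12 at 1.05, adjusted p = 0.365, and FIT3 at -0.74, adjusted p = 0.505). Leaving out MA-A3 against MA-A1 ended 5, among them the 4 named for MA-A1 with MA-A0 or MA-A8 (adjusted p from 0.0631 to 0.0956), and leaving out MA-A1 against MA-A4 ended 5. The model without the dye term and the robust prior ended 4 each, leaving out MA-A8 against MA-A1 3, and leaving out MA-A1 against MA-A0 or MA-A4 against MA-A8 1 each.

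The pairs with MA-A3 had the most differing genes: 988 against MA-A8 (584 higher and 404 lower in MA-A3), 818 against MA-A1 (270 higher and 548 lower in MA-A1), 629 against MA-A0 (215 higher and 414 lower in MA-A0) and 628 against MA-A4 (434 higher and 194 lower in MA-A3). Without genes on the shifted chromosomes 3 of these splits turned. MA-A3 then had 195 higher and 265 lower against MA-A8 and 77 higher and 127 lower against MA-A4, and MA-A0 had 121 higher and 83 lower against MA-A3. The other pairs had 125 for MA-A1 and MA-A4, 118 for MA-A4 and MA-A8, 99 for MA-A0 and MA-A1, 95 for MA-A0 and MA-A4, 23 for MA-A0 and MA-A8 and 12 for MA-A1 and MA-A8. At an unadjusted p under 0.05 the 10 pairs had between 477 genes (MA-A0 and MA-A8) and 1616 (MA-A3 and MA-A8). Each pair was joined directly by 1 array, and most of these counts moved over 1.5 times when 1 array was left out. Without the MA-A0 against MA-A8 array MA-A0 differed from MA-A1 in 810 genes, from MA-A3 in 1183, from MA-A4 in 417 and from MA-A8 in 63, and there were 316 for MA-A1 and MA-A4, 67 for MA-A1 and MA-A8 and 187 for MA-A4 and MA-A8. Omitting MA-A3 against MA-A1 left 231 for that pair, 383 for MA-A0 and MA-A3, 57 for MA-A0 and MA-A4, 14 for MA-A1 and MA-A4 and 73 for MA-A4 and MA-A8. For this omission limma's test called 0 for MA-A0 and MA-A1 (964 at an unadjusted p under 0.05) and 0 for MA-A1 and MA-A8 (737). Omitting MA-A3 against MA-A0 left 176 for that pair, 5 for MA-A0 and MA-A1, 38 for MA-A0 and MA-A4, 57 for MA-A1 and MA-A4 and 7 for MA-A1 and MA-A8. Omitting MA-A8 against MA-A1 left 14 for MA-A0 and MA-A1, 54 for MA-A0 and MA-A4, 2 for MA-A0 and MA-A8, 545 for MA-A1 and MA-A3, 19 for MA-A1 and MA-A4, 19 for MA-A4 and MA-A8 and with limma 0 for its own pair (433 at an unadjusted p under 0.05). Omitting MA-A8 against MA-A3 left 461 for that pair, 13 for MA-A0 and MA-A8, 22 for MA-A1 and MA-A8 and 71 for MA-A4 and MA-A8. Omitting MA-A4 against MA-A8 left 17 for that pair, 14 for MA-A0 and MA-A8 and 5 for MA-A1 and MA-A8. Omitting MA-A1 against MA-A4 left 1 for that pair, 2 for MA-A0 and MA-A1, 30 for MA-A0 and MA-A4, 9 for MA-A0 and MA-A8, 36 for MA-A4 and MA-A8 and with limma 0 for MA-A1 and MA-A8 (755 at an unadjusted p under 0.05). Omitting MA-A1 against MA-A0 left 2 for that pair, 28 for MA-A0 and MA-A4, 4 for MA-A0 and MA-A8, 39 for MA-A1 and MA-A4 and 7 for MA-A1 and MA-A8. Omitting MA-A4 against MA-A3 left 336 for that pair, 36 for MA-A0 and MA-A8, 57 for MA-A1 and MA-A4, 55 for MA-A1 and MA-A8 and 76 for MA-A4 and MA-A8. Omitting MA-A0 against MA-A4 left 18 for that pair and 43 for MA-A0 and MA-A1, and gave 131 for MA-A1 and MA-A8. With values as deposited the split turned for MA-A0 and MA-A3 (65 genes, 52 higher and 13 lower in MA-A0).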

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

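Of the tests in this part, those of the chromosome shifts, those of the MA-A0 against MA-A8 array and those of the stress genes on shifted chromosomes and of growth were chosen after the result was seen, whereas the counts over other assignments of the lines (but for the sizes of the chromosome medians) and the effect of single arrays on the stress genes were planned. The MA-A0 against MA-A8 array lay far from the others in the share of its variance that lay between blocks of consecutive probe rows, 31.7% against 13.8% for the next array, a ratio of gap to range of 0.61 with a limit of 0.47. Chance puts about 1 in 20 measures beyond this limit, and 8 measures were compared. The array also ran against the other 9: its values correlated at -0.21 with those predicted for it from the rest, and its weight in the model with array weights was 0.258. A trend along the probe order was not the whole of it, since after centring within blocks the correlation was still -0.107. The idea that MA-A1, MA-A3 or MA-A4 was on it in place of a labelled line was argued against by chromosomes XIII, XII and IX, which were displaced by at most 0.04 there and by at least 0.18 in 12 of 12 combinations of a chromosome with an array of its line. An earlier test of that idea, the highest correlation with the values predicted for any of 18 other ordered pairs (0.375), decided nothing and was replaced. An exchange of its 2 channels cannot be told apart from a weak array: of the 63 genes that differed between MA-A0 and MA-A8 without it, 61 had a value on it and 30 of these (49.2%) went the labelled way on it, near the share that chance gives, which keeps it open. The array was kept as labelled wherever the text does not say that it was left out or its sign turned.

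The displacement of chromosomes XIII, XII, IX and XI was weighed against technical sources and a change in copy number. A trend along the probe order was argued against, since centring within blocks left at least 94.0% of each median, and a single deviating array was argued against, since 16 of 16 combinations of array and chromosome were displaced in the direction of the line. If cells held 2 copies of each chromosome, a number the labels do not give, a gain of 1 with expression following dose would give 0.58 in log2 and 0.41 in natural logarithms. In the opposite direction a loss of 1 would give 1 and 0.69 in size. Bins of XIII in MA-A3 reached from 0.36 to 0.73 in size, which spans these values but for a loss in log2. Bins of XII, IX and XI reached at most 0.37 in size. A change of copy number in every cell cannot be told apart from other causes for any of the 4 chromosomes, since the direction, the base and the number of copies, which set the size of a gain or loss, are not given. A change in part of the cells, or ratios compressed by the arrays, was not tested. Over 100 random assignments of the arrays to pairs of lines, the real one included, 1 gave a chromosome median as large (0.56, against a highest other of 0.46). This makes chance unlikely for the size of XIII in MA-A3. The other 3 were each set against the chromosomes left after the larger ones were taken out. A median as large as that of XII was given by 1 of the 100 (0.25, highest other 0.245) and as that of IX by 2 (highest other 0.245). Such low numbers make chance less likely for these 2 chromosomes but do not exclude it. For XI 6 gave a median as large (0.11, highest other 0.128), and chance is not excluded. It is also not excluded for the count of chromosomes, planned first, since 81 of the 100 gave as many as the real 12 and the highest other gave 22. The arrays keep their displaced chromosomes whatever lines they are assigned to, a structure of the samples.

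The high level of general stress genes in MA-A3 and their low level in MA-A8 were weighed next. Members on shifted chromosomes, 13 of the 27 that were higher in MA-A3, did not account for the whole of it. Without them 67.9% of the median was left in MA-A3 (0.39 of 0.58) and 114% in MA-A8. No single array carried the pattern, with at least 84.2% left in each line. Slower growth of MA-A3 or faster growth of MA-A8, in which ribosomal proteins would be lower or higher, cannot be told apart from other causes. Those genes were lower in MA-A8 on 3 of its 4 arrays with the dye effect removed and on 2 without removing it, and lower in MA-A3 on 2 of 4 either way, and the rule that asked for the same answer both ways was set after they were seen. The state of the cultures at harvest cannot be separated from the line.

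Counts were also set against the 100 assignments, as the number giving as many genes and the highest of the others. For genes differing among the lines it was 1 (1014, with a highest other of 85). For pairs it was 1 for MA-A0 and MA-A1 (99, highest other 63), 1 for MA-A0 and MA-A3 (629, 70), 2 for MA-A0 and MA-A4 (95, 407), 1 for MA-A0 and MA-A8 (23, 18), 1 for MA-A1 and MA-A3 (818, 154), 3 for MA-A1 and MA-A4 (125, 275), 1 for MA-A3 and MA-A4 (628, 187), 1 for MA-A3 and MA-A8 (988, 58) and 1 for MA-A4 and MA-A8 (118, 11). These lie under the planned limit of 5 of 100. That limit was not corrected over the many counts, so chance is made less likely for them but is not excluded. For MA-A1 and MA-A8 it was 5 (12, highest other 274), which is not under the limit. For single lines it was 1 for MA-A0 (18, highest other 10), 1 for MA-A1 (206, 160), 1 for MA-A3 (919, 82), 3 for MA-A4 (194, 294) and 1 for MA-A8 (180, 83), each under the limit. For lists among the lines it was 1 (9, highest other 3), also under it. For lists per line it was 5 (56, highest other 64), where chance is left open. Assignments that called several times the real count, as for MA-A0 and MA-A4 or MA-A1 and MA-A8, point to a structure of the arrays. Those with 407, 275 and 274 genes had largest chromosome medians of 0.41, 0.43 and 0.43, against 0.16, 0.09 and 0.12 without XIII. They thus kept a large displacement of XIII, which the arrays of MA-A3 carry. Whether this accounts for their counts was not tested, and another assignment with a largest median of 0.44 called 0 genes.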

How the results depend on the processing

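Counts of genes depended on the spread model and on single arrays. Over 3596 comparisons of 174 results for named genes none that passed turned, and 19 results were the same in every alternative. The genes were named for large differences or small p-values in these data, and every alternative reuses most of the arrays. That none turned is therefore no independent test of their directions. Results that passed neither in the fit used here nor in an alternative also count as the same, so the 19 need not be calls that held. Of 952 comparisons of 56 list results 15 turned, 7 of them with values as deposited. For the counts the cause of a move was not tested unless it is named. Counts are given in the order in which the report has them: among the lines, then pairs, then each line against the mean of the other 4. Without a dye term the counts were 580 among the lines (580 of them shared), 395 for MA-A0 and MA-A3, 36 for MA-A0 and MA-A4, 7 for MA-A0 and MA-A8, 530 for MA-A1 and MA-A3, 21 for MA-A1 and MA-A4, 41 for MA-A4 and MA-A8, 6 in MA-A0, 28 in MA-A1, 59 in MA-A4 and 72 in MA-A8, and limma called 0 for MA-A0 and MA-A1 (864 at an unadjusted p under 0.05) and 0 for MA-A1 and MA-A8 (688). With values as deposited there were 145 among the lines (137 of them shared), 6 for MA-A0 and MA-A1, 65 for MA-A0 and MA-A3, 10 for MA-A0 and MA-A4, 5 for MA-A0 and MA-A8, 72 for MA-A1 and MA-A3, 3 for MA-A1 and MA-A4, 3 for MA-A1 and MA-A8, 77 for MA-A3 and MA-A4, 112 for MA-A3 and MA-A8, 5 for MA-A4 and MA-A8, 5 in MA-A0, 5 in MA-A1, 176 in MA-A3, 4 in MA-A4 and 15 in MA-A8. By construction these fits keep the offset of each array as noise. The split of the called genes moved by over 10 percentage points there in 9 contrasts, as higher and lower 4 and 2 for MA-A0 and MA-A1, 52 and 13 for MA-A0 and MA-A3, 9 and 1 for MA-A0 and MA-A4, 9 and 63 for MA-A1 and MA-A3, 2 and 1 for MA-A1 and MA-A4, 42 and 35 for MA-A3 and MA-A4, 5 and 0 in MA-A0, 1 and 3 in MA-A4 and 2 and 13 in MA-A8. Medians that turned there were those of gluconeogenesis (0.16), sulphur amino acid synthesis (0.13), the iron regulon (0.0675), flocculation (0.12) and subtelomeric families (0.16) in MA-A0, ribosome biogenesis in MA-A1 (-0.0675), the iron regulon in MA-A8 (-0.035), chromosomes XII (0.22) and XIII (0.18) in MA-A0 and XI in MA-A1 (-0.00125). The median of all genes was itself 0.28 in MA-A0, -0.14 in MA-A1 and -0.07 in MA-A8. Each of the turned medians stayed on the same side of it. With arrays scaled to the same spread there were 15 for MA-A0 and MA-A8, 380 for MA-A1 and MA-A4, 42 for MA-A1 and MA-A8 (27 higher and 15 lower), 311 for MA-A4 and MA-A8 (148 higher and 163 lower), 389 in MA-A1 and 303 in MA-A4. With genes measured on all 10 arrays alone there were 39 for MA-A1 and MA-A8. Array weights gave 1867 among the lines, 346 for MA-A0 and MA-A1, 1220 for MA-A0 and MA-A3, 266 for MA-A1 and MA-A4, 253 for MA-A1 and MA-A8, 332 for MA-A4 and MA-A8, 40 in MA-A0, 588 in MA-A1, 1460 in MA-A3 and 337 in MA-A8. A robust prior gave 78 for MA-A1 and MA-A8 and 30 in MA-A0. The unmoderated test, on 5 residual degrees of freedom, gave 62 among the lines, 175 for MA-A0 and MA-A3, 370 for MA-A1 and MA-A3, 198 for MA-A3 and MA-A4, 472 for MA-A3 and MA-A8 and 577 in MA-A3, and called 0 for MA-A0 and MA-A1 (961 at an unadjusted p under 0.05), MA-A0 and MA-A4 (734), MA-A0 and MA-A8 (420), MA-A1 and MA-A4 (851), MA-A1 and MA-A8 (818), MA-A4 and MA-A8 (746), MA-A0 (667), MA-A1 (1017), MA-A4 (726) and MA-A8 (888). Added afterwards, centring within blocks of probe rows gave 87 for MA-A1 and MA-A8 (52 higher and 35 lower) and 186 for MA-A4 and MA-A8. Turning the sign of the MA-A0 against MA-A8 array, also added, gave 1537 among the lines, 643 for MA-A0 and MA-A1, 1319 for MA-A0 and MA-A3, 302 for MA-A0 and MA-A4, 34 for MA-A1 and MA-A8, 75 for MA-A4 and MA-A8, 639 in MA-A0, 332 in MA-A1 and 6 in MA-A8, and limma then called 0 for MA-A0 and MA-A8 (1102 at an unadjusted p under 0.05). It turned glycolysis in MA-A0 (-0.0565), ribosomal proteins (0.0705), the proteasome (-0.0221) and histones (0.0075) in MA-A8 and the excess of varying a-specific genes (-3.39 percentage points). Without genes on the shifted chromosomes, the last alternative added, 4120 genes were tested, so counts fell by construction, to 428 among the lines, 59 for MA-A0 and MA-A1, 204 for MA-A0 and MA-A3, 61 for MA-A0 and MA-A4, 222 for MA-A1 and MA-A3, 74 for MA-A1 and MA-A4, 5 for MA-A1 and MA-A8, 204 for MA-A3 and MA-A4, 460 for MA-A3 and MA-A8, 76 for MA-A4 and MA-A8, 10 in MA-A0, 42 in MA-A1, 361 in MA-A3, 1.2e+02 in MA-A4 and 96 in MA-A8. The split moved by over 10 percentage points in 9 contrasts, as higher and lower 41 and 18 for MA-A0 and MA-A1, 121 and 83 for MA-A0 and MA-A3, 24 and 50 for MA-A1 and MA-A4, 1 and 4 for MA-A1 and MA-A8, 77 and 127 for MA-A3 and MA-A4, 195 and 265 for MA-A3 and MA-A8, 15 and 27 in MA-A1, 159 and 202 in MA-A3 and 73 and 50 in MA-A4. With an estimated correlation camera called 0 lists per line (17 at an unadjusted p under 0.05) and 2 chromosomes (14). Leaving out 1 array at a time the counts ranged over 591 to 1906 among the lines, 0 to 810 for MA-A0 and MA-A1, 176 to 1183 for MA-A0 and MA-A3, 18 to 417 for MA-A0 and MA-A4, 2 to 63 for MA-A0 and MA-A8, 231 to 1126 for MA-A1 and MA-A3, 1 to 316 for MA-A1 and MA-A4, 0 to 131 for MA-A1 and MA-A8, 336 to 833 for MA-A3 and MA-A4, 461 to 1117 for MA-A3 and MA-A8, 17 to 187 for MA-A4 and MA-A8, 0 to 448 in MA-A0, 0 to 576 in MA-A1, 565 to 1227 in MA-A3, 16 to 310 in MA-A4, 33 to 254 in MA-A8, 52 to 60 lists per line, 6 to 11 lists among the lines and 11 to 15 chromosomes. Medians turned without MA-A0 against MA-A4 (general stress in MA-A4, -0.12325 to 0.00725 over the omissions), without MA-A4 against MA-A8 (glycolysis in MA-A8, -0.0723 to 0.458), without MA-A0 against MA-A8 (glycolysis in MA-A0, -0.0515 to 0.333) and without MA-A8 against MA-A1 (ribosome biogenesis in MA-A1, -0.046 to 0.13175), and the cause was not tested.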

Other observations

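All observations in this part were chosen after the values were seen, but for genes named by the rule. Single genes named by the rule differed among the lines although their lists did not pass Fisher's exact test (adjusted p = 0.286 for hexose transporters, 1 for galactose genes and 0.445 for nitrogen catabolite genes). The hexose transporter gene HXT2, on chromosome XIII, was higher in MA-A3 by 1.09 ± 0.13 and lower in MA-A8 by -0.86 ± 0.13, and GAL10 was at 0.58 ± 0.10 in MA-A8 and -0.55 ± 0.10 in MA-A4. In MA-A4 the peroxisomal citrate synthase gene CIT2, a target of mitochondrial retrograde signalling, was higher by 0.87 ± 0.11 (adjusted p = 0.00116), and the ammonium permease gene MEP3 by 0.61 ± 0.10. The sterol genes ERG28 and ERG26 were lower in MA-A3 by -0.74 ± 0.11 and -0.63 ± 0.11 and higher in MA-A8 by 0.53 ± 0.11 and 0.45 ± 0.11. In MA-A3 8 members of the ergosterol list were lower and 5, all on chromosome XIII, were higher, and the list did not pass camera (adjusted p = 0.0634). Without genes on the shifted chromosomes the list was lower there, with a median of -0.28 (camera with the preset correlation, adjusted p = 3.0e-05). The pheromone-induced genes PRM5 and PRM4 were lower in MA-A3 by -0.70 ± 0.11 and -0.67 ± 0.11, whereas FUS2, on chromosome XIII, was higher by 0.55 ± 0.11. Their list had 3 members lower and 2 higher in MA-A3 and did not pass camera (adjusted p = 0.112). OPI3, of phosphatidylcholine synthesis, was at 0.63 ± 0.12 in MA-A0 and -0.61 ± 0.12 in MA-A4. With values as deposited the F test no longer called GAL10, CIT2, MEP3, ERG28, ERG26, PRM5, PRM4 and FUS2. Without MA-A8 against MA-A3 FUS2 did not pass it either (adjusted p = 0.0574).

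No test was made of the genes of the mitochondrial genome as a group. In MA-A0 the median of 16 such genes was -0.31 and 0 of 16 lay above 0, while 14 of 16 lay above 0 in MA-A1 (median 0.23) and in MA-A4 (0.13), 13 in MA-A8 (0.11) and 2 in MA-A3 (-0.18). Of the 16, BI3 passed the F test (adjusted p = 0.0249), with -0.82 in MA-A0. Among reading frames of Ty1 retrotransposons, which were neither counted nor tested as a group, 2 that were picked by eye were lower in MA-A3. YAR009C was at -1.18 ± 0.15 (adjusted p = 7.1e-05) and YJR027W at -1.27 ± 0.22 (adjusted p = 0.000897). Of 817 probe rows without a gene name that could be tested, 1 passed the F test (0.122%), against 18.7% of named genes.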
